A study of Drosophila melanogaster with 36 samples.

How the data were processed

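ChIP-seq, RNA-seq, small RNA-seq and GRO-seq libraries came from ovaries of adult flies after germline knockdown of rhino, deadlock, cutoff or piwi, or a control knockdown. The labels list 36 libraries. Groups were taken from the labels: 2 libraries each for control and piwi knockdown Rhino ChIP, for H3K9me3 ChIP in control, rhino and piwi knockdown, for input and for control RNA-seq, and 1 library for each other group. The 3 libraries of capped RNA and of H3K4me2 ChIP were not analysed here. A column of sequenced genomic DNA reads and other annotation not named below were not used here.

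The authors deposited a single table with 139714 bins of 1 kb on the dm3 assembly, with decimal commas. Per the labels, the upstream tools were cutadapt 1.0, Bowtie 0.12.7, GSNAP, SAMtools 0.1.16 and bedtools 2.16.1, without a statement of which tool made which column. The deposited values are a normalised signal per bin that the labels do not define further. Dividing out the mappability index and a constant per library gave whole reads in 100% of bins under 500 reads, within 0.1 read, for all 21 columns that hold 1 library. The value was thus the number of reads scaled to a library total, divided by the mappability index of the bin, plus an offset of 0.1, or of 0.01 for RNA-seq. The other 6 columns used are averages of 2 libraries that the authors made before deposit, and no reads could be recovered for them. Strands were not separated in the table. Summed bin reads came to 102.4% to 104.8% of the library total for ChIP and GRO-seq and 110.7% to 110.8% for RNA-seq. For small RNA they came to 89.7% in the control, 41.3% to 45.2% in the knockdowns and 14.6% in the Piwi immunoprecipitate. What the small RNA totals were set to is not stated.

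Bins were kept where the input average was at least 25% of the median input of 8.71, which left 123742 bins. Changes were computed as differences of log2(value + 1) per bin and summarised as medians over the bins of a region, with distribution-free 95% binomial intervals over bins. Neighbouring bins are not independent, so these intervals describe the spread along a region and not that between animals. For single libraries, the ratio of summed scaled reads was given with an exact Clopper-Pearson 95% interval conditional on the sum of the reads. Intervals cover counting error only and not the spread between ovaries.

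A bin was called Rhino-bound where the control Rhino ChIP average was at least 4-fold over the input average on the log2(value + 1) scale. Bound bins with gaps of up to 3 kb were joined, and a domain needed at least 5 bound bins. The medians of listed regions were set beside 10000 random sets of as many bins from outside the listed regions, matched on mean signal in 20 strata, and the share of sets with a lower median was given as a percentile. The sets were scattered bins, so their medians spread less than those of contiguous regions if neighbouring bins change together. The highest stratum had no upper limit, so regions of very high signal could be set beside weaker bins. A percentile describes the libraries at hand, and no p-value was computed. For RNA-seq, bins were counted that lay below or above both control libraries in all 3 knockdowns.

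The regions and the rules for naming items were fixed before the data were examined. Named were the 10 listed regions, which are 5 dual-strand clusters, 2 clusters transcribed from 1 strand and 3 chromosome ends, and the 10 domains of bound bins with the largest summed control Rhino signal over input. Genes were not named, since no annotation on dm3 was used, and the transcripts of the knocked-down genes themselves were not analysed here. Other bins are named only where the text says that they were chosen after their values were seen.

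Planned tests of single bins with limma or edgeR for H3K9me3 and Rhino ChIP, the tests of region classes with fry and camera, and the rule that each control replicate be bound needed separate replicates and were not run, because the values used were averages. Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no input filter, an input filter of 50%, rescaling to equal arm medians, binding thresholds of 2-fold and 8-fold, and leaving out each RNA-seq control library. Alternatives added after seeing the data were the bins of the authors' window selection, a mappability index of at least 0.5, leaving out the distal chromosome 4 cluster or 42AB, scaling of small RNA to flamenco, and leaving out the bin with the most small RNA reads of a region. Bins without reads in either library have a log2 change of 0 by construction.

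The procedure was tested on simulated data with 139714 bins, of which 200 changed. Reads were recovered in 100% of simulated values. The intervals covered the true ratio in 97% of the changed bins for small RNA and 96.5% of those for Pol II. An 8-fold loss gave median log2 changes of -2.73 for small RNA and -1.55 for Pol II, and a 2-fold loss gave -0.97 and -0.71, so the pseudocount shrinks changes where signal is low. Of 100 unchanged sets, 8 and 7 lay below percentile 5. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.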

Results

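Ovaries of adult flies aged 4 to 6 days were profiled after germline knockdown of rhino, deadlock, cutoff or piwi, or after a control knockdown. Rhino is a chromodomain protein of the HP1 family, and Deadlock and Cutoff are its partner proteins at piRNA clusters, the loci that give rise to the small RNAs bound by Piwi-family proteins. The labels list 36 libraries, of which 33 were represented by signal per 1 kb bin of the dm3 assembly. Chromatin immunoprecipitation (ChIP) was done for Rhino, Deadlock, Cutoff, trimethylated lysine 9 of histone H3 (H3K9me3) and RNA polymerase II (Pol II). RNA was measured as small RNA of 18 to 29 nt, as total RNA without ribosomal RNA (RNA-seq) and as nascent RNA from a nuclear run-on (GRO-seq).

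The control Rhino ChIP, the piwi knockdown Rhino ChIP, the H3K9me3 ChIP of the control, rhino knockdown and piwi knockdown, and the input each came as an average of 2 libraries made by the authors, with no spread. RNA-seq of the control had 2 separate libraries, and every other group had 1 library. Replicate error could therefore be given for the RNA-seq control alone, and no comparison had a test across replicates. Library totals used for scaling were 8780000, 3872000 and 20239997 reads for Rhino ChIP in rhino, deadlock and cutoff knockdown. They were 10420000 and 8170000 for Deadlock ChIP in the control and its own knockdown, 13329999 and 19040000 for Cutoff ChIP in the control and its own knockdown, and 23820000 and 19040000 for Pol II ChIP in the control and rhino knockdown. GRO-seq had 7070000 in the control and 6659999 in rhino knockdown. RNA-seq had 110809998 and 36289999 in the control libraries and 123340000, 64300000 and 169659999 in rhino, deadlock and cutoff knockdown. Small RNA totals were 4190000, 4940000, 4510000 and 6340000 in the control and in rhino, deadlock and cutoff knockdown, and 43999998 for the small RNA bound to Piwi in piwi knockdown. The depth of the averaged libraries is unknown.

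Rhino in the control covered the dual-strand clusters, which are transcribed from both strands, far more densely than the chromosome arms. Signal was at least 4-fold over input in 270 of 313 bins (86.3%) of the 5 dual-strand clusters and in 378 of 110515 bins (0.342%) of the euchromatic arms. Cluster 42AB (2R 2144001 to 2387000, no annotated exon in the bins kept) was bound in all of its 166 bins kept, with a median log2 signal over input of 5.57 (95% interval over bins 5.31 to 5.70). The medians were 3.52 at cluster 80F (3L 23273001 to 23315000), 3.07 at the distal chromosome 4 cluster (4 1258001 to 1349000), 2.63 at cluster 38C2 (2L 20104001 to 20117000) and 2.53 at cluster 38C1 (2L 20148001 to 20228000). Among the chromosome ends, which carry telomere-associated repeats, the 3R end (27895001 to 27905000) had a median of 4.68 over 4 bins, the 2L end (1 to 10000) 2.19 over 5 bins and the 2R end (21136001 to 21147000) 2.03 over 10 bins.

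The clusters transcribed from 1 strand carried less Rhino. The medians were 1.39 at flamenco (X 21503001 to 21685000), the main cluster of the somatic follicle cells, with 18 of 89 bins bound, and 0.94 at the germline cluster 20A (X 21392001 to 21432000), with 2 of 19 bins bound. Of the 4143 bound bins, 2911 (70.3%) lay on the unassembled heterochromatic scaffolds, 427 at the pericentromeric ends of the arms and 124 on chromosome 4. The authors' own Rhino peaks held 1048 of all bound bins, 466 of those on the scaffolds and 0 of those at flamenco. By the same rule, 285 bins not bound in the control were called bound in rhino knockdown. A call is therefore not proof of Rhino occupancy. Joining bound bins within 3 kb gave 197 domains of at least 5 bound bins. The 10 domains with the largest summed signal over input were 3 in 42AB, 1 in 80F, 4 on 3LHet, 1 on 3RHet (2070001 to 2113000) and 1 on chromosome 4 (810001 to 874000, 57 bound bins, exon overlap in 22.8% of them). The first of the 42AB domains (2R 2136001 to 2200000) began before the listed start of the cluster. The number of bound bins depended on the threshold and filter, from 961 with mappability of at least 0.5 to 11600 with a 2-fold rule. The distal chromosome 4 cluster differed between its parts: its 20 bins inside the authors' own window selection had a median of 1.08.

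The Rhino ChIP libraries from the knockdowns address whether Rhino occupies chromatin without its partners. Rhino signal over the dual-strand clusters was lower in all 3 knockdowns of the complex, with median log2 changes of -3.85 (-4.10 to -3.37) in rhino, -3.71 (-3.95 to -3.40) in deadlock and -3.36 (-3.58 to -3.02) in cutoff knockdown. At 42AB the mean signal per bin was 467 in the control and 15.5, 21.5 and 19.5 in these knockdowns. All 166 bins of 42AB were lower in each of them, with medians of -5.06, -4.64 and -4.54. The 3R end had medians of -4.76, -5.09 and -3.75, and the domain on chromosome 4 had -3.25, -3.30 and -2.35. All 10 of the strongest domains were lower in each of the 3 knockdowns. In the euchromatic arms the medians were 0.16, 0.15 and 0.17.

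By the 4-fold rule, 755, 762 and 1027 bins were bound in rhino, deadlock and cutoff knockdown, of which 22, 39 and 12 lay in the dual-strand clusters. The medians of the dual-strand clusters were below all 10000 random sets of bins matched on mean signal in 20 strata in each of these libraries. Cluster 38C2 was an exception: its medians of -1.23 and -0.87 in rhino and deadlock knockdown stood at percentiles 7.57 and 19.1 of its random sets, and -2.14 in cutoff knockdown at percentile 0.19. At 20A the medians were -1.18, -1.33 and -0.04. Without 42AB the class medians were -2.23, -2.56 and -2.04. With 1 library per knockdown, these percentiles describe the libraries and not the variation between ovaries. The random sets were scattered bins while each cluster is contiguous, so their medians vary less than those of neighbouring bins would. The highest stratum had no upper limit. Mean control Rhino signal was 354 over the dual-strand clusters against 36.5 on the heterochromatic scaffolds and 8.46 in the euchromatic arms. The sets could therefore hold weaker bins, whose changes the pseudocount shrinks more, so a place below all sets may partly follow from the matching.

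Knockdown of piwi, whose product directs H3K9me3 to its targets, went with a smaller change of Rhino signal over the dual-strand clusters; the difference between knockdowns was not tested. The median log2 change over the dual-strand clusters was -0.96 (-1.11 to -0.84), and 240 of their bins were still bound, 234 of them also bound in the control. At 42AB the mean signal was 198 against 467 in the control, with a median of -1.24 (-1.32 to -1.18). The medians were -1.47 (-1.75 to -0.17) at the distal chromosome 4 cluster, -0.59 at 80F and -2.86 at the 3R end. At 38C1 the median was 0.02 (-0.36 to 0.53).

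Cluster 38C2 went the other way. Rhino signal there was higher in piwi knockdown in all 13 bins, with a mean of 210 against 63.1 and a median change of 1.42 (0.545 to 2.49), above all 10000 random sets. Across the genome 3242 bins were bound in piwi knockdown, of which 803 were not bound in the control. Such bins also numbered 285 of 755 in rhino, 247 of 762 in deadlock and 341 of 1027 in cutoff knockdown. The class median was -0.40 without 42AB and -0.50 in bins with mappability of at least 0.5. At the distal chromosome 4 cluster the 20 bins inside the authors' window selection had a median of 0.05 (-0.02 to 0.33).

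**Figure D1:**
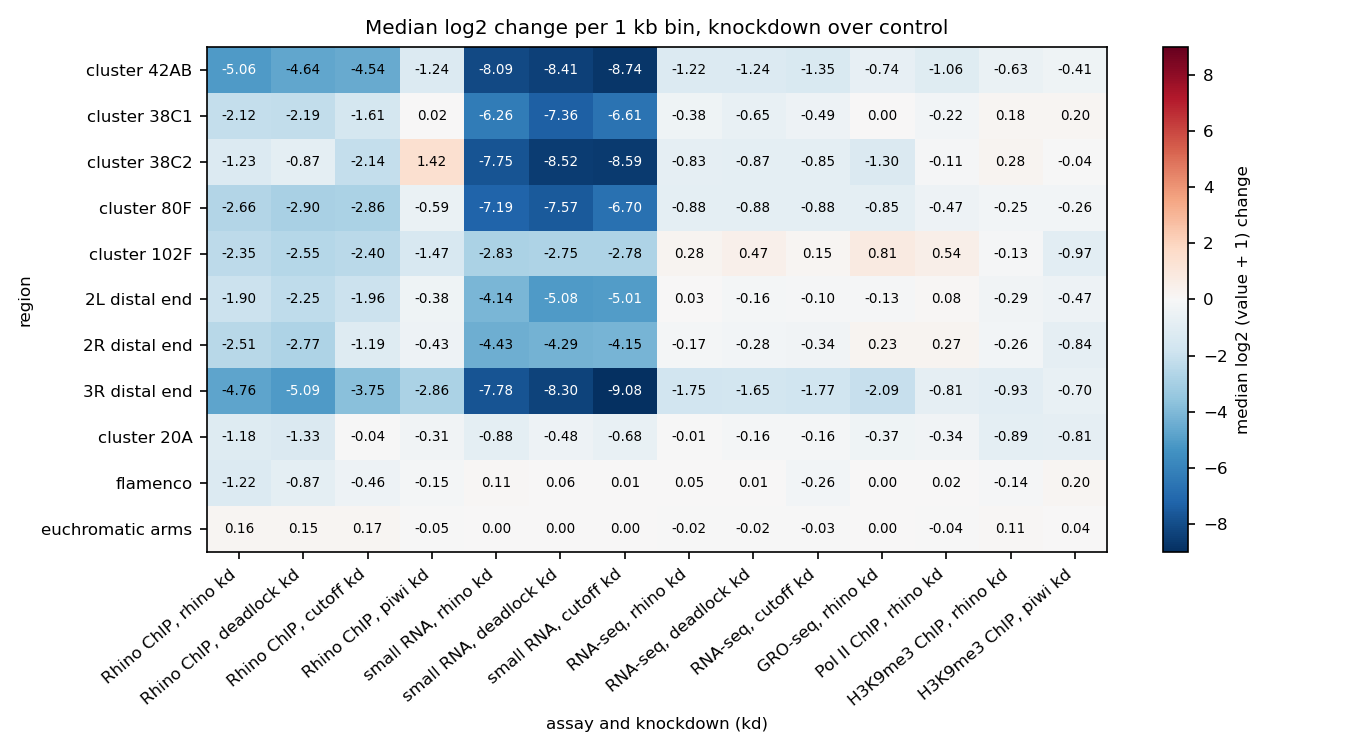
Median log2 change per 1 kb bin of each region (vertical axis) for each assay and knockdown (horizontal axis), as numbers and colour, with euchromatic arms in the last line. Small RNA had medians between -9.08 and -2.75 at the dual-strand clusters and chromosome ends and between -0.88 and 0.11 at cluster 20A and flamenco.

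Deadlock and Cutoff were both enriched at the dual-strand clusters when compared with the same ChIP in their own knockdown. The median log2 ratio was 1.28 (1.02 to 1.56) for Deadlock and 0.82 (0.63 to 1.05) for Cutoff, both above all 10000 random sets. At 42AB the summed reads were 7.06-fold (6.85 to 7.27) higher in the control than in the own knockdown for Deadlock and 3.53-fold (3.46 to 3.60) for Cutoff. For Deadlock the medians were 0.78 at 80F, 0.76 at 38C2, and 0.63 at 38C1 and the distal chromosome 4 cluster. For Cutoff they were 0.83 at 38C2, 0.62 (-0.02 to 1.30) at 80F, 0.12 (-0.11 to 0.69) at 38C1 and -0.02 (-0.20 to 0.31) at the distal chromosome 4 cluster. Flamenco had -0.34 for Deadlock and -0.31 for Cutoff.

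Over all 4143 Rhino-bound bins the median log2 ratio to the own knockdown was smaller, 0.32 (0.28 to 0.36) for Deadlock and -0.02 (-0.06 to 0.00) for Cutoff. The summed reads of these bins were 1.93-fold (1.91 to 1.94) higher in the control for Deadlock and 1.27-fold (1.26 to 1.27) for Cutoff. Over input, the same bins had medians of 0.97 for Deadlock and 0.87 for Cutoff. The Cutoff ratio to its own knockdown was low in heterochromatin as a whole. Summed reads gave 0.862 over all kept scaffold bins, 0.845 at the pericentromeric ends and 0.704 on chromosome 4, against 1.01 in the euchromatic arms. In the bound scaffold bins the ratio was 1.06. A Cutoff log2 ratio near or below 0 therefore does not show that Cutoff was absent. With bins bound at least 8-fold the median log2 ratios to the own knockdown were 0.94 and 0.53, and with bins bound at least 2-fold they were -0.17 and -0.40. Without 42AB the class median for Cutoff was 0.28, and for Deadlock it was 0.70.

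Small RNA from the dual-strand clusters was far lower in each knockdown of the complex, while the clusters transcribed from 1 strand stayed closer to the control. Mean signal per bin at 42AB was 3670 in the control and 30.1, 27.8 and 24.1 in rhino, deadlock and cutoff knockdown, and the summed reads were 94.3-fold (92.5 to 96.2), 97.9-fold (95.9 to 99.9) and 114-fold (112 to 117) lower. A single bin of 42AB (2R 2325001 to 2326000, mappability index 0.514), chosen after its values were seen, held 65.7%, 64.8% and 71.7% of the cluster's reads in these knockdowns. Without it the summed reads were 268-fold (259 to 277), 271-fold (262 to 281) and 395-fold (381 to 409) lower. In rhino knockdown the summed reads were 77.2-fold lower at 38C1, 180-fold at 38C2 and 122-fold at 80F, and in deadlock and cutoff knockdown they were 79.8-fold to 422-fold lower at these 3 clusters. At the 3R end, 5922 reads in the control compared with 21, 15 and 9 reads, which is 332-fold (217 to 538), 425-fold (257 to 760) and 996-fold (524 to 2178) lower. Flamenco had ratios of knockdown to control of 1.08, 1.11 and 1.01, and 20A had 1.12, 1.15 and 1.31, with median log2 changes per bin of -0.88 (-1.22 to 0.379), -0.48 and -0.68 at 20A. At 20A the bin with the most reads (X 21394001 to 21395000), chosen after its values were seen, held 38.8%, 32.2% and 41.4% of the reads in the knockdowns, and without it the summed reads were 1.30-fold, 1.15-fold and 1.17-fold lower.

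The distal chromosome 4 cluster had summed reads 7.84-fold, 3.61-fold and 6.27-fold lower, and 7.60-fold, 8.28-fold and 7.35-fold lower in its 20 bins inside the authors' window selection. The 2L end had 5.52-fold, 5.69-fold and 4.45-fold fewer reads, or 40.8-fold, 83.9-fold and 70.2-fold fewer without its bin at 9001 to 10000, chosen after its values were seen, and the 2R end 15.6-fold, 14.2-fold and 12.7-fold fewer. All 10 of the strongest Rhino domains had less small RNA in each knockdown, with median log2 changes from -9.52 in 42AB to -5.24 at the chromosome 4 domain in cutoff knockdown. Over the dual-strand clusters the medians were -7.36 (-7.60 to -7.09), -7.83 (-8.02 to -7.60) and -7.57 (-7.94 to -7.17), each below all 10000 random sets. These sets could hold weaker bins, since mean control signal was 2381 over the dual-strand clusters against 99.2 on the heterochromatic scaffolds. Summed bin reads were 89.7% of the scaling total in the control but 41.3%, 44.4% and 45.2% in the knockdowns, and what the totals were set to is not stated. Scaling to equal flamenco reads gave -7.37, -7.91 and -7.54.

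**Figure D2:**
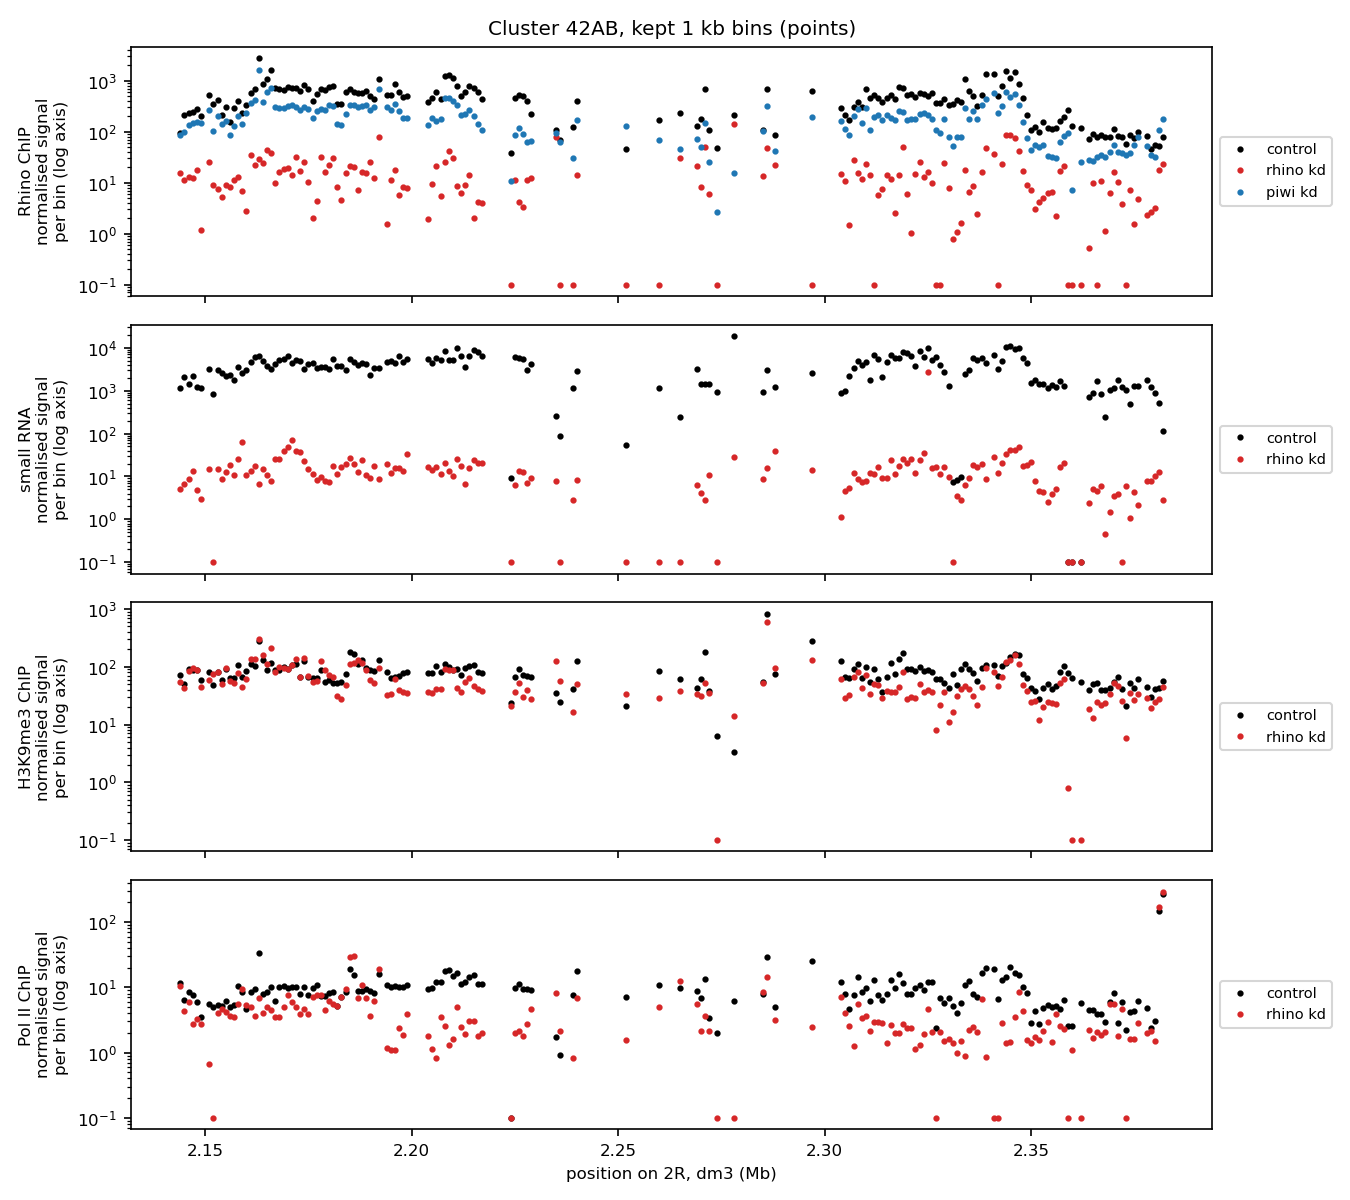
Normalised signal per kept 1 kb bin (log axes) along cluster 42AB on 2R (Mb, dm3) for Rhino ChIP, small RNA, H3K9me3 ChIP and Pol II ChIP, with control, rhino knockdown and, for Rhino ChIP, piwi knockdown as points; points at 0.1 are bins without reads. Mean Rhino signal was 467 in the control, 198 in piwi and 15.5 in rhino knockdown.

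The RNA bound to Piwi in piwi germline knockdown, labelled as somatic piRNA, mapped to a different set of clusters. Its mean signal was 991 per bin at flamenco, where the control small RNA library had 1129. It was 235 at 20A against 6597 in the control library, 6.19 at 42AB against 3670 and 2.49 at 80F against 990. This library was 1 immunoprecipitate without a control of its own kind, so its levels were set beside total small RNA.

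RNA-seq asked whether the long transcripts of the clusters changed together with their small RNA. In the bins inside the authors' window selection, a restriction chosen after the data were seen, mean signal over the dual-strand clusters was 2.74 ± 0.576 (SD, n = 2) in the control and 1.42, 1.73 and 1.12 in rhino, deadlock and cutoff knockdown. At 42AB it was 3.17 ± 0.742 (SD, n = 2) against 1.28, 1.74 and 0.592. Cluster 38C2 had 0.987 ± 0.048 (SD, n = 2) against 0.322, 0.331 and 0.276, cluster 38C1 had 0.992 ± 0.109 (SD, n = 2) against 0.410, 0.163 and 0.211, and the 3R end had 2.75 ± 0.475 (SD, n = 2) against 0.0261, 0.0971 and 0.0255. Means were closer to the control at 80F, with 4.55 ± 0.963 (SD, n = 2) against 3.62, 4.11 and 4.39, and at the distal chromosome 4 cluster, with 0.569 ± 0.0572 (SD, n = 2) against 0.524, 0.644 and 0.431. The mean at 80F does not describe most of its bins. Median signal over its 41 kept bins was 1.26 and 1.42 in the control libraries against 0.109, 0.0936 and 0.160 in the knockdowns. Flamenco had 2.05 ± 0.143 (SD, n = 2) against 2.29, 2.59 and 1.69. The 2R end was higher in all 3 knockdowns, at 1.22 ± 0.166 (SD, n = 2) against 2.74, 2.65 and 2.77, while its median changes were -0.17, -0.28 and -0.34.

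Per bin, 200 of 313 bins (63.9%) of the dual-strand clusters were below both control libraries in all 3 knockdowns and 35 (11.2%) were above both. If each knockdown value were drawn with the controls by chance, 10% would fall on each side, and in the euchromatic arms 18.9% were below and 8.01% above. The bins below both controls in all 3 knockdowns were 125 of 166 at 42AB, 33 of 41 at 80F, 27 of 39 at 38C1 and 11 of 13 at 38C2. At the distal chromosome 4 cluster 4 of 54 were below and 26 above.

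The median log2 changes over all kept bins of the dual-strand clusters were -0.73 (-0.88 to -0.63), -0.83 (-0.94 to -0.66) and -0.89 (-1.01 to -0.78), against -0.07 between the control libraries. The means over the same bins were 2.55 ± 0.404 (SD, n = 2) in the control against 2.60, 3.91 and 1.81. The mean was thus higher than both control libraries in deadlock knockdown, between them in rhino knockdown and lower than both in cutoff knockdown. In each knockdown the bins of low mappability named below raised this mean, so its direction does not describe most bins. Over all kept bins the means of the clusters differed in direction. The means were 3.05 ± 0.605 (SD, n = 2) in the control against 2.14, 2.90 and 0.936 at 42AB and 4.45 ± 0.991 (SD, n = 2) against 3.36, 3.81 and 4.10 at 80F. They were above both controls in each knockdown at 38C1, with 1.37 ± 0.202 (SD, n = 2) against 4.08, 9.52 and 3.16, and at the distal chromosome 4 cluster, with 0.797 ± 0.404 (SD, n = 2) against 2.96, 3.91 and 2.164. A bin of 42AB with a mappability index of 0.038 (2R 2185001 to 2186000), chosen after its values were seen, went from 2.17 to 154, 222 and 62.1. A bin of 38C1 (2L 20161001 to 20162000, mappability index 0.021) was also chosen after its values were seen. Its signal went from 11.014 in the control to 144.4, 363.63 and 114.52 in rhino, deadlock and cutoff knockdown. It lay outside the authors' window selection. In the 33 bins of 38C1 inside that selection the means were below the control, at 0.410, 0.163 and 0.211 against 0.992. Pseudocounts of 0.1 and 5 in place of 1 gave medians over the dual-strand clusters of -1.90 and -0.23 in rhino knockdown, and leaving out 42AB gave -0.31.

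GRO-seq and Pol II ChIP in rhino knockdown addressed transcription itself, and the clusters did not move together. At 42AB Pol II reads summed to 0.599 of the control (0.582 to 0.617), with a median log2 change of -1.06 (-1.30 to -0.908), and GRO-seq reads to 0.898 (0.851 to 0.947), with a median of -0.74. Pol II signal was higher in rhino knockdown in bins at the right edge, chosen after their values were seen. It went from 148 to 173 at 2R 2381001 and from 274 to 294 at 2R 2382001, where the control mean of the cluster was 11.4. The summed Pol II ratio includes these bins, so it lies above that of the other bins of 42AB. The Rhino domains there differed. The Pol II and GRO-seq medians were -0.47 and 0.40 at 2R 2136001 to 2200000, which begins before the cluster. They were -2.09 and -2.99 at 2204001 to 2218000 and -1.20 and -1.56 at 2304001 to 2383000. At 80F the ratios were 0.787 (0.744 to 0.834) for Pol II and 0.651 (0.591 to 0.717) for GRO-seq, and at the 3R end 0.492 (0.389 to 0.619) and, from 4 reads against 37, 0.115 (0.0297 to 0.319). The distal chromosome 4 cluster was higher, with ratios of 1.83 (1.79 to 1.88) for Pol II and 2.31 (2.157 to 2.477) for GRO-seq. In its 20 bins inside the authors' window selection the ratios were 1.02 (0.963 to 1.09) and 1.00 (0.857 to 1.17).

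Clusters 38C1 and 38C2 had higher sums but not higher medians. Pol II reads summed to 1.30 (1.25 to 1.35) at 38C1 and 1.39 (1.34 to 1.44) at 38C2, with medians of -0.22 and -0.11, and GRO-seq reads to 2.01 (1.85 to 2.18) and 1.12 (1.05 to 1.20), with medians of 0.00 and -1.30. At 38C1, 12 of 39 bins had no GRO-seq reads in either library, which holds their change at 0. A few bins, chosen after their values were seen, held most of these reads. At the edge of 38C2 (2L 20104001 to 20105000) Pol II signal was 157 in the control and 237 in rhino knockdown, and near the edge of 38C1 (2L 20223001 to 20224000) GRO-seq signal was 59.7 and 157, with 990 of the 1640 GRO-seq reads of the cluster in rhino knockdown. The bin of 38C1 with the highest Pol II signal (2L 20148001 to 20149000) had 130 and 174 for Pol II but 16.2 and 16.3 for GRO-seq.

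Over the dual-strand clusters the Pol II median was -0.52 (-0.67 to -0.44) and the GRO-seq median -0.39 (-0.70 to 0.00), both below all 10000 random sets, but the ratios of summed reads were 1.16 and 1.25. Median and sum therefore differed in direction for the class. Class medians depended on the bins used. Without 42AB they were 0.01 (-0.15 to 0.14) for Pol II and 0.00 (-0.40 to 0.0560) for GRO-seq, and without the distal chromosome 4 cluster -0.74 (-0.91 to -0.65) and -0.71 (-0.95 to -0.29). In the authors' window selection they were -0.66 (-0.79 to -0.48) and -0.84 (-1.13 to -0.60), and with mappability of at least 0.5 -0.34 (-0.52 to -0.21) and -0.73 (-0.94 to -0.47). In the euchromatic arms the ratios were 0.998 for Pol II and 0.975 for GRO-seq. The arms held 23811278 of 24734237 Pol II reads and 6694489 of 7238581 GRO-seq reads in the control. Scaling to library totals thus holds these ratios near 1, and they do not show that transcription of the arms was unchanged.

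H3K9me3, the mark that Rhino binds, was enriched at the dual-strand clusters in the control, with a median log2 signal over input of 2.80 (2.69 to 2.89), and at flamenco, with 2.24. In rhino knockdown the median change over the dual-strand clusters was -0.35 (-0.45 to -0.22), and the clusters differed. It was -0.63 (-0.74 to -0.52) at 42AB, -0.25 at 80F and -0.93 at the 3R end, but 0.18 at 38C1 and 0.28 at 38C2. The mean at 42AB was 84.4 in the control and 60.3 in rhino knockdown. Along 42AB the median change was -0.13 in the Rhino domain at 2R 2136001 to 2200000. It was -0.96 in that at 2204001 to 2218000 and -0.84 in that at 2304001 to 2383000. Cluster 20A, where little Rhino was bound, had -0.89 (-1.10 to -0.436), and the Rhino domain on 3RHet had 0.91.

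In piwi knockdown the median over the dual-strand clusters was -0.37 (-0.43 to -0.32), with -0.97 (-1.18 to -0.757) at the distal chromosome 4 cluster, -0.41 at 42AB and 0.20 at 38C1. Cluster 20A had -0.81 and flamenco 0.20, and the heterochromatic scaffolds had 0.33 (0.32 to 0.34). The medians of 42AB were below all 10000 random sets of scattered bins in both knockdowns. Runs of as many H3K9me3-rich unbound bins, taken in order along each chromosome and skipping other bins, varied more. After subtraction of the median change of unbound bins of the same mean signal, 3 of 75 such runs lay as low as 42AB in rhino knockdown. The run medians went from -0.82 to 0.57. These runs could span gaps, so they do not give the spread of contiguous regions. Without 42AB the class median in rhino knockdown was -0.06, and the arm median moved by 0.15 in that knockdown, so changes relative to the arms were lower by that amount. The values are averages of 2 libraries without spread, so the difference between replicates could not be set beside these changes.

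**Figure D3:**
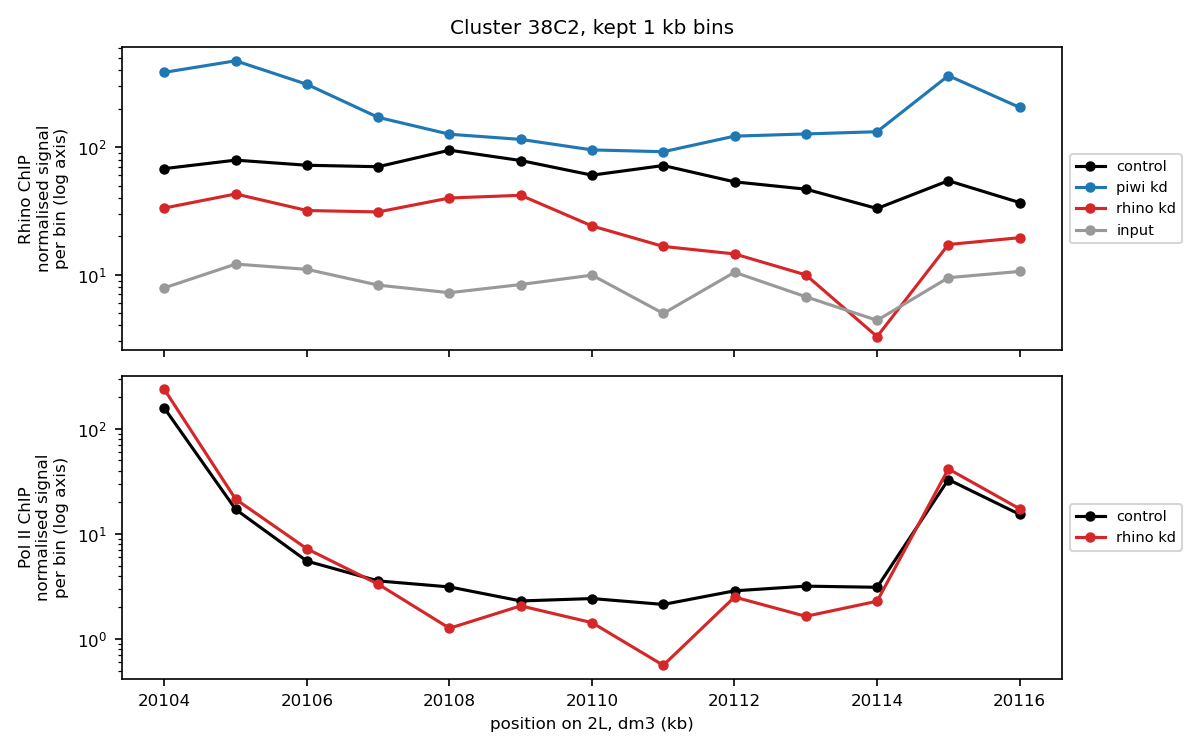
Normalised signal per kept 1 kb bin (log axes) along cluster 38C2 on 2L (kb, dm3) for Rhino ChIP with input (top) and Pol II ChIP (bottom), each line a knockdown or control. Rhino signal in piwi knockdown lay above the control in all 13 bins, with a mean of 210 against 63.1.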

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

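The limits were the following. Alternatives covered 19 results with 14 alternatives, which gave 180 values, of which 68 were the same, 110 moved and 2 changed sign from a median whose interval excluded 0, called reversed here. A further 4 sign changes, counted among those that moved, were of Cutoff ChIP at Rhino-bound bins, whose original median of -0.02 had an interval that reached 0. A median counted as the same inside the 95% interval of the original, an RNA-seq median if it differed by less than the SD of the values without each control library, and the number of bound bins if it differed by less than 1.5-fold. The alternatives on the authors' window selection, mappability, the distal chromosome 4 cluster, 42AB, flamenco and the bin with the most small RNA reads were chosen after seeing the data. No paired analysis was possible because the values used were authors' averages or single libraries, and RNA-seq, with 2 control libraries, had 1 library per knockdown and thus no pairs, so a replicate block was not run. No test was planned for RNA-seq. For H3K9me3 and Rhino ChIP, averages also ruled out limma with and without trend, edgeR, DESeq2, fry and camera, the arms and chromosome 4 alone, binding in control replicate 1 or 2 alone, and Rhino ChIP or H3K9me3 without each replicate. The depth of single libraries limits values at small regions, and the depth of the averages is unknown. Unless stated, the cause of a difference was not tested.

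In the lists below, medians refer to the dual-strand clusters unless Rhino-bound bins are named, and 3 values in a row stand for rhino, deadlock and cutoff knockdown. With a pseudocount of 5, there were 2333 Rhino-bound bins, Rhino ChIP gave -3.23 in deadlock and -3.02 in cutoff knockdown, Deadlock and Cutoff ChIP at Rhino-bound bins 0.55 and 0.25, small RNA -6.74, -7.01 and -6.89, RNA-seq -0.23, -0.24 and -0.26, and Pol II -0.29. With 0.1, Deadlock and Cutoff at Rhino-bound bins gave 0.18 and -0.17, small RNA -7.61 in rhino and -8.17 in deadlock knockdown, and RNA-seq -1.90, -2.18 and -2.20. A larger pseudocount shrinks changes of low signal by construction.

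With input of at least 50% of the median, there were 2210 Rhino-bound bins, Deadlock and Cutoff at them gave 0.56 and 0.24, and RNA-seq -0.77 in rhino and -0.85 in deadlock knockdown. With no filter on input, Rhino ChIP gave -2.64, -2.79 and -2.45, and -0.63 in piwi knockdown. Deadlock and Cutoff gave 0.0546 and -0.15 at Rhino-bound bins and 0.47 and 0.0574 at the clusters, small RNA -5.84, -6.13 and -5.93, RNA-seq -0.34, -0.40 and -0.50, Pol II 0.00, and H3K9me3 -0.0614 in rhino and -0.16 in piwi knockdown. Of the 156 bins this added to the clusters, 101 had a mappability index of 0, so their log ratio was 0 by construction.

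With libraries rescaled to equal arm medians, Deadlock and Cutoff at Rhino-bound bins gave 0.19 and -0.0885, small RNA -7.07 in rhino and -7.54 in deadlock knockdown, RNA-seq -0.68, -0.76 and -0.81, and H3K9me3 -0.50 in rhino knockdown. With a 2-fold rule for binding there were 11600 Rhino-bound bins, and Deadlock reversed to -0.17 there, with Cutoff at -0.40. With an 8-fold rule there were 1517 Rhino-bound bins, with 0.94 for Deadlock and 0.53 for Cutoff. Without each RNA-seq control library in turn, RNA-seq ranged from -0.77 to -0.73 in rhino, -0.78 to -0.76 in deadlock and -0.90 to -0.82 in cutoff knockdown.

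With the authors' window selection alone, there were 2125 Rhino-bound bins, Rhino ChIP in piwi knockdown gave -0.83, RNA-seq -0.90, -0.94 and -1.01, GRO-seq -0.84 and H3K9me3 in piwi knockdown -0.30. With mappability of at least 0.5, there were 961 Rhino-bound bins and Rhino ChIP gave -2.69, -2.86 and -2.18, and -0.50 in piwi knockdown. Deadlock and Cutoff gave 0.53 and 0.11 at Rhino-bound bins and 0.70 and 0.37 at the clusters, small RNA -6.81, -7.57 and -6.87, RNA-seq -0.64, -0.72 and -0.73, GRO-seq -0.73, Pol II -0.34 and H3K9me3 in piwi knockdown -0.25.

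Without the distal chromosome 4 cluster, Rhino ChIP gave -4.19, -3.96 and -3.65, Deadlock 1.66, Cutoff 1.11, small RNA -7.70, -8.16 and -8.11, RNA-seq -0.96, -1.002 and -1.08, GRO-seq -0.71 and Pol II -0.74. Without 42AB, Rhino ChIP gave -2.23, -2.56 and -2.04, and -0.40 in piwi knockdown, Deadlock 0.70, Cutoff 0.28, small RNA -5.65, -6.13 and -5.57, RNA-seq -0.31, -0.40 and -0.38, and H3K9me3 -0.0637 in rhino and -0.29 in piwi knockdown. Pol II reversed to 0.0095. With small RNA scaled to flamenco, 3 of 3 values stayed the same. Summed small RNA reads, kept apart from these counts, were also taken without the bin with the most reads. At 42AB they then were 268-fold, 271-fold and 395-fold lower in place of 94.3-fold, 97.9-fold and 114-fold, and at 20A the ratios changed from above 1 to below 1.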

Other observations

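Regions, filters and the 4-fold binding rule were fixed before the data were examined. Tests chosen after the results were seen were those of H3K9me3 at Rhino-bound bins, of scaling and of edge and inner bins at cluster 38C2, of low-input and of well mapped bins and their spread at the distal chromosome 4 cluster, and the interval applied at 42AB. The other tests were chosen before their values were seen.

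The authors' own division of small RNA source bins followed the chromatin classes. Bins marked as Rhino-dependent numbered 6954, of which 81.2% were heterochromatic and 7.26% overlapped an exon, and 31.7% of those kept were Rhino-bound. Rhino-independent bins numbered 1662, with 52.3% heterochromatic, 45.0% exon overlap and 7.36% bound, and somatic bins numbered 2565, with 17.9% heterochromatic, 75.6% exon overlap and 2.05% bound. The first 2 classes separated at a ratio of rhino knockdown to control small RNA of 0.203, so they rest on the same libraries and their rhino knockdown values are not independent evidence. The values gave no such limit in the other knockdowns: of the Rhino-dependent bins, 97.6% and 98.1% were also at most 0.203 of the control in deadlock and cutoff knockdown, against 17.0% and 12.5% of the Rhino-independent bins. All ratios share 1 control library. Observed were 6790 and 6819 bins low in both rhino and the other knockdown, against 5709 and 5672 for independent calls of the same sizes. In 100 simulations that kept this shared control, at most 2 and 3 bins were low in both. These simulations left rhino knockdown unchanged too, so a low count followed from their setup and does not weigh on the overlap.

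Rhino-bound bins outside the listed regions had less small RNA in rhino knockdown, with medians of -4.49 over 124 bins on chromosome 4 and -5.02 over 2911 bins on the heterochromatic scaffolds. RNA-seq was below both control libraries in all 3 knockdowns in 79.0% of the bound bins of chromosome 4, against 39.4% of all its bins. The same values were 43.1% against 18.9% on the euchromatic arms, 173 of 427 against 1366 of 3620 bins at the pericentromeric ends and 24.5% against 24.7% on the scaffolds, and no difference between these classes was tested. On chromosome 4 the bound bins had medians in rhino knockdown of -0.72 (-0.84 to -0.55) for RNA-seq, -0.43 (-0.50 to -0.35) for Pol II and -0.62 (-0.77 to -0.40) for GRO-seq. On the scaffolds 57.4% of bound bins had no GRO-seq reads in either library, so their GRO-seq median is uninformative. Summed reads there were 1.72 of the control for GRO-seq and 1.27 for Pol II, although the Pol II median was -0.18. Over all kept bins of the scaffolds the ratios were 1.52 for GRO-seq and 1.18 for Pol II, so a rise was not particular to bound bins. At the 2R end, Pol II reads in rhino knockdown summed to 1.40 (1.31 to 1.504) of the control and GRO-seq reads to 2.29 (1.96 to 2.68), beside small RNA reads 15.6-fold lower.

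H3K9me3 at 42AB was lower in rhino knockdown by a median of -0.63. After subtraction of the change of unbound bins of the same mean signal the remainder was -0.32 (-0.42 to -0.202). Loss of the mark wherever Rhino is bound would leave the 3840 bound bins outside the listed regions below 0. Their remainder was 0.0831 (0.0535 to 0.106), which argues against a loss over these bins as a set. Only 1048 of all 4143 bound bins lay in the authors' Rhino peaks, so a loss limited to strongly bound chromatin stays open. Before subtraction, the 10 strongest domains had medians from -0.96 to 0.91, higher only at the 3RHet domain. Weaker enrichment of the whole rhino knockdown average cannot be told apart from a change at 42AB: 4.0% of 75 runs of H3K9me3-rich unbound bins lay as low, under the limit of 5% set beforehand, but the exact 95% interval added later (0.833% to 11.2%) spans that limit. Cluster 20A, with little Rhino, had a remainder of -0.90, and a biological cause stays untested.

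Rhino signal at 38C2 was higher in piwi knockdown, by 1.42 in the median. Higher ChIP signal at Pol II-rich chromatin would raise euchromatic unbound bins of the same Pol II signal. Over all 13 bins of 38C2 the matched bins had a median of -0.0836. This value cannot test such an effect, since 9 of the 13 were inner bins where Pol II did not exceed input. The 4 edge bins, where Pol II exceeded input, were higher by 2.53. Bins matched to them were also higher, by 0.442 (0.262 to 0.861 per edge bin), which was less than the rise of the edge bins. The 9 inner bins were higher by 1.18 against -0.0879 in matched bins. The matched bins were all unbound, so they cannot exclude such an effect at bound bins rich in Pol II. Rhino signal also changed in Pol II-rich bins of other clusters, picked after their values were seen. It rose from 50.3 to 266 at 2L 20148001 in 38C1 and from 52.5 to 107 at 2R 2381001 in 42AB. It also rose from 17.1 to 87.5 at 2L 20223001 in 38C1, and from 79.0 to 175 at 2R 2382001 in 42AB. At 4 1292001 in the distal chromosome 4 cluster it rose from 142 to 169. It fell from 1959 to 411 at 4 1287001 in that cluster, a bin with an input of 147 against a median of 8.71. At 2R 2163001 in 42AB, with a Pol II signal of 34.0, it fell from 2749 to 1598. Whether the rise follows Pol II across the clusters was not tested. Rescaling to equal arm medians gave 1.492 at 38C2, since the arm median moved by only -0.0718. A shift shared with the arms thus does not account for the rise. If the averages were scaled to library totals, close arm medians follow from that scaling, so this is a weak test. A change in Rhino placement through loss of Piwi stays open and untested, since the values are averages of 2 libraries.

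Pol II and GRO-seq signal at the distal chromosome 4 cluster was higher in rhino knockdown, with summed ratios of 1.83 and 2.31. Reads from repeated copies in bins with high input cannot be told apart from a change at the cluster. In the 26 low-input bins the ratios were 1.89 (lower bound 1.797) for Pol II and 1.32 (1.141) for GRO-seq, against 1.81 and 2.71 in the high-input bins, but these bounds cover counting error only and the low-input medians of 0.24 (-0.15 to 0.83) and 0.37 (-0.41 to 1.89) had intervals that reached below 0. Few mappable positions cannot be told apart either: the 20 bins of the authors' window selection had ratios of 1.02 (lower bound 0.9629) and 1.00 (0.857), but the 20 bins with mappability of at least 0.5 had 1.78 and 1.92, mostly through 4 bins outside the selection with 2.43 and 3.34, and medians of 0.0094 (-0.22 to 0.37) and 0.31 (-0.86 to 0.70) that decide nothing. Mean control Rhino signal was 15.7 in the bins of the selection against 451 over all 54 bins, so a biological change at the Rhino-rich bins stays open.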
